A study of Drosophila melanogaster with 6 samples.

How the data were processed

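Messenger RNA was measured by RNA sequencing in the S2 line, an established cell line made from Drosophila melanogaster embryos. Cells received double-stranded RNA (dsRNA), which these cells take up and which silences the gene of matching sequence. Per the labels, 1 group received dsRNA against beta-galactosidase, a bacterial gene absent from the fly genome, and serves as the control. The other 2 groups received dsRNA 2 or dsRNA 3 against Hlc, a DEAD-box RNA helicase. Each of the 3 groups holds 2 libraries described as biological replicates, sampled on day 3. Libraries were made from polyadenylated RNA with a TruSeq RNA kit, per the labels' protocols.

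The authors deposited a single table of whole-number counts per annotated feature, with no normalization, in 1 column per library. Trimmomatic 0.36, TopHat2 2.1.0, StringTie 2.1.7 and genome build BDGP6 are named without roles, per the submitters' processing notes. The counting step, its treatment of multi-mapping reads and its strand setting are not given in the sources used here. Counts of near-identical gene copies, of overlapping genes and of genes with an antisense partner are therefore uncertain in how reads were divided. In every library more features stood at a count of 1 than at 2 (697 against 333 in control replicate 1). The cause was not tested, so the lowest counts are taken as uncertain. No column of per-sample values was left unused, and columns were assigned to libraries by name.

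The table holds 23882 features, of which 7410 were at 0 in every library. Feature identifiers were matched to the Ensembl annotation of assembly BDGP6.54, release 115, where 99.7% were found. Gene positions, exonic lengths and feature classes come from that annotation and are 1-based. Library totals ran from 56195472 to 84283999 counts. Replicates differed by more than sampling noise (chi-square per degree of freedom 29.6, 34.0 and 41.0 in the control, dsRNA 2 and dsRNA 3 groups), so each library was counted as 1 replicate.

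Tests were run in R 4.3.3 on the deposited counts. Features were kept by filterByExpr, scaled with TMM factors and tested with the quasi-likelihood F test of edgeR 4.0.16, in 1 fit of all 6 libraries with a term per group. All groups shared the estimate of the spread, which had 3 residual degrees of freedom before moderation. The contrasts were the mean of both Hlc dsRNAs minus control, dsRNA 2 minus control, dsRNA 3 minus control, and dsRNA 3 minus dsRNA 2. A feature was called at a Benjamini-Hochberg adjusted p under 0.05 among 11293 tested. Standard errors (SE) of log2 fold changes were taken as the absolute fold change divided by the square root of F. Such an SE is a scale implied by the test and does not measure the error of very large changes or of genes near 0 counts. CG10814, at 0 counts with dsRNA 3, had a fitted log2 fold change of -10.4 with an SE of 0.63 in that contrast. CPM denotes counts scaled to TMM-adjusted library size by the cpm function of edgeR, given as mean ± SD.

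The design, the alternatives, the rule for named genes and 23 gene lists were fixed before the data were examined. The rule named Hlc and MtnA, the 10 largest rises and 10 largest falls with both dsRNAs, and the 5 largest each way in the other contrasts. It also named up to 4 members of each list with the smallest adjusted p. The largest rises and falls had to be called, to have a mean of at least 50 counts in the higher group, and to carry a symbol other than a CG or CR number. In the contrast of both dsRNAs they also had to move the same way with each dsRNA, with all 4 Hlc libraries on one side of both controls. Lists were tested with camera from limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01, adjusted over the 23 lists, with an estimated correlation and fry as companions.

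The alternatives were DESeq2 size factors, upper-quartile factors and library size alone in place of TMM, no filter or 1 CPM in at least 4 libraries in place of filterByExpr, DESeq2 1.42.0 and limma-voom as tests, the replicate number as a block, each library left out in turn, and fits of only the groups compared. A fit with the trend on exonic length removed and a fit with transposable element copies summed to families were chosen after seeing the data. For the overlap of calls between dsRNAs, 20 data sets with unchanged groups against the same controls were simulated. Counting intervals are exact binomial at 95%, and a group at 0 was bounded by 3 counts over the whole group. Both cover counting error only.

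The fit was tested on simulated data with 200 changed genes. In the contrast of both dsRNAs, among 10879 features kept, it recovered 74.7% of 95 genes changed 2-fold and 89.4% of 94 changed 4-fold, with 8 false calls. The simulated contrast between the dsRNAs, where nothing was changed, gave 1 call. A simulated list of 27 shifted members was called by camera, and 0 of 50 unchanged lists passed an unadjusted p of 0.05. Rises and falls were balanced among the 200 genes, whereas 7321 of 11293 features were called in the data. Members of simulated lists varied independently. The simulation therefore does not test the scaling where most features change, nor camera where members of a list correlate.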

Results

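The study asked how loss of the DEAD-box helicase Hlc changes transcript levels in S2 cells, with an interest in the basal transcription of stress-responsive genes. Poly(A) RNA was sequenced from 6 libraries on day 3, namely 2 control libraries (beta-galactosidase dsRNA), 2 with Hlc dsRNA 2 and 2 with Hlc dsRNA 3. Totals were 64881683 and 77803482 counts in the controls, 71563233 and 56195472 with dsRNA 2, and 57376417 and 84283999 with dsRNA 3. In both controls the most abundant feature was AttB, which codes for the antimicrobial peptide Attacin-B (23490 ± 274 CPM, SD, n = 2). In the 4 Hlc libraries the most abundant feature was eEF1alpha1, a translation elongation factor (7757 ± 575 CPM, SD, n = 4).

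The target transcript was low in every library that received Hlc dsRNA. Hlc (FBgn0001565, chromosome X, 21385518 to 21387946, minus strand) stood at 316 ± 1.15 CPM in the controls (SD, n = 2) and 18.7 ± 1.80 CPM in the Hlc libraries (SD, n = 4). The log2 fold change was -4.08 (SE 0.07, adjusted p 3.48e-08). It was -4.15 (SE 0.10) with dsRNA 2 and -4.01 (SE 0.10) with dsRNA 3, and no difference between the dsRNAs was called (log2 difference 0.14, adjusted p 0.456). The lowest control level was 15.8 times the highest level in an Hlc library, so Hlc separated the controls from the Hlc dsRNA libraries. It cannot check for a swap between the dsRNA 2 and dsRNA 3 groups.

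Comparing both Hlc dsRNAs with control, the deepest falls among genes named by the rule were mostly in heat shock and immune genes. The best measured large rise was in the cell cycle gene stg. The 10 largest falls named by the rule were Hsp70Bc, Hsp70Ba, Hsp70Bbb, Hsp70Bb, Hsp70Aa, Hsp70Ab, Hdc, AttD, AttC and spirit. AttD, an attacin without a secretion signal, went from 4165 ± 90.2 CPM to 8.84 ± 2.43 CPM, and AttC from 1202 ± 54.3 to 2.69 ± 0.26 CPM (SD, n = 2 and 4). Hdc, histidine decarboxylase, had 152 counts over the controls and 0 over the Hlc libraries. It was 143-fold lower when bounded by 3 counts over the group, and the 95% counting interval started at 115. spirit, which codes for a serine protease of the Toll pathway, had 4562 counts against 37, a ratio of 348 (95% counting interval 252 to 496). With dsRNA 2 replicate 2 left out the other dsRNA 2 library held 0 counts of spirit, and its fitted log2 fold change went from -8.59 to -11.25.

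The 10 largest rises were Tsp5D, GABA-B-R2, Syn1, TM4SF, stg, btn, aos, by, 2mit and mir-2a-2. The best measured was stg, the Cdc25 phosphatase that triggers entry into mitosis, which rose from 19.2 ± 0.02 to 322 ± 19.2 CPM (log2 fold change 4.07, SE 0.07, adjusted p 3.53e-08). aos, a secreted inhibitor of the EGF receptor, rose from 3.91 ± 0.60 to 57.2 ± 4.38 CPM, btn, a homeobox gene, from 4.91 ± 0.26 to 76.6 ± 11.9 CPM, and by, the fly tensin, from 1.35 ± 0.18 to 16.8 ± 1.34 CPM. Syn1, a syntrophin, rose from 33 counts over the controls to 1792 over the Hlc libraries. The others had almost no control counts. Tsp5D, a tetraspanin, had 5 against 1024 (ratio 72.5, interval 31.0 to 224), and GABA-B-R2, a GABA receptor subunit, had 3 against 324 (ratio 38.2, interval 13.0 to 186). TM4SF had 5 against 248, 2mit 7 against 250 and mir-2a-2 6 against 205, the last sharing 61.1% of its exonic bases with another gene and not called once the length trend was removed (adjusted p 0.0542). In each of these 5 genes 1 control library held all the control counts. Without control replicate 2 the log2 fold changes were 4.98 for Tsp5D and 4.04 for GABA-B-R2, and without control replicate 1 they were 3.22 for TM4SF, 2.73 for 2mit and 2.71 for mir-2a-2. Leaving out the library with the counts left the control at 0.

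In all, 7321 of 11293 features were called (64.8%), 3634 higher and 3687 lower, of which 1687 rose and 1495 fell more than 2-fold. The split between rises and falls depended on the scaling, because the controls carried TMM factors of 0.751 and 0.778 against 1.13 to 1.16 in the Hlc libraries. Upper-quartile factors called 4245 higher and 3152 lower with the median of all features at 0.19 on the log2 scale, and library size alone called 6331 higher and 1815 lower with the median at 0.62, against 0.04 with TMM. Directions below are on the TMM scale and are qualified where another scaling turned them.

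**Figure D1:**
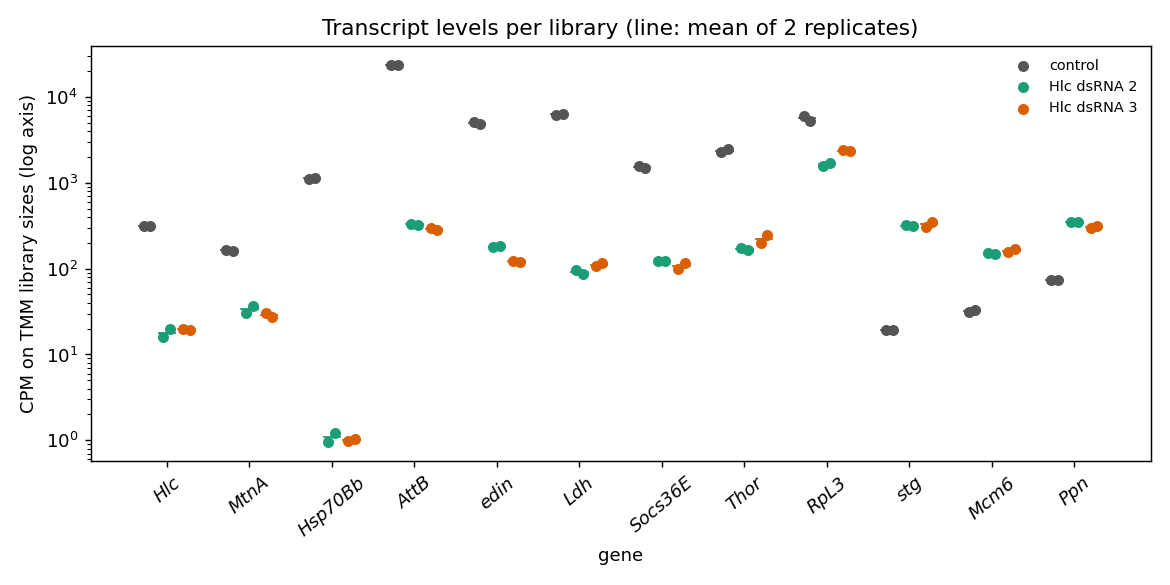
Transcript levels of 12 genes in each library, as CPM on TMM library sizes on a log axis, with 1 point per library and a short line at the mean of 2 replicates. The 2 control libraries lie above all 4 Hlc libraries for Hlc (316 against 18.7 CPM on average) and below them for stg (19.2 against 322 CPM).

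Heat shock genes, chaperones whose transcripts rise when proteins unfold, were lower as a group. All 19 measured members fell, with a median log2 fold change of -6.03. The median was -6.83 with dsRNA 2 and -4.95 with dsRNA 3, with 0 members called between the dsRNAs. Hsp70Bbb went from 875 ± 15.3 to 0.75 ± 0.08 CPM (log2 fold change -10.19, SE 0.06, adjusted p 6.00e-10), and Hsp70Aa, Hsp70Bc and Hsp70Ab had log2 fold changes of -10.04, -10.41 and -9.95. The 6 Hsp70 genes are near-identical copies, so the division of reads among them is uncertain. The SE of a fall this deep is a scale implied by the test and does not measure its error. The other 13 members ranged from -8.27 (Hsp26) to -0.92 (Hsp60A), both named after their values were seen. The list was called by camera (adjusted p 3.25e-11), but not with an estimated correlation (adjusted p = 0.0600 with an estimated correlation).

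Effectors and regulators of the Imd and Toll immune pathways were also lower, with 23 of 26 members lower, 2 higher and 1 not called, and a median of -5.08. AttB (chromosome 2R, 14749223 to 14750165) went from 23490 ± 274 to 309 ± 22.1 CPM (log2 fold change -6.25, SE 0.06, adjusted p 1.59e-09), although reads may be shared with its close copy AttA. PGRP-LB, a peptidoglycan-degrading enzyme, had a log2 fold change of -5.10 (SE 0.05), and edin, a small immune-induced peptide, went from 4971 ± 98.2 to 151 ± 34.6 CPM. The 2 that rose, spz (1.88) and Dif (0.66), code for the ligand and a transcription factor of the Toll pathway and were named after their values were seen. Camera called the list (adjusted p 3.93e-11; adjusted p = 0.0600 with an estimated correlation).

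The metal response list had 5 lower, 1 higher and 1 not called among 7 members (median -0.91), and 4 lower and 1 higher with library size alone (median -0.33). MtnA, a metallothionein that binds copper and other metals (chromosome 3R, 9783407 to 9784370), fell from 163 ± 5.19 to 31.3 ± 4.02 CPM (log2 fold change -2.38, SE 0.08, adjusted p 5.23e-07). The zinc transporter ZnT63C (-2.30, SE 0.04) and the copper transporter ATP7 (-2.07, SE 0.06) fell as well. ZnT86D was at -0.46 (SE 0.05), a fall that became 0.12 and was not called with library size alone. Camera gave the list an adjusted p of 0.0180 (adjusted p = 0.182 with an estimated correlation).

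Glutathione and oxidative stress genes had 27 lower, 1 higher and 9 not called among 37 (median -1.25), and 18 lower and 7 higher with library size alone (median -0.66). The glutathione transferase GstE9 went from 1140 ± 47.1 to 55.6 ± 1.51 CPM (-4.36, SE 0.05), with GstE11 at -3.69, Gclm, a subunit of the enzyme that starts glutathione synthesis, at -2.03 and the autophagy receptor ref(2)P at -1.91. Camera gave adjusted p 1.54e-07 (adjusted p = 0.182 with an estimated correlation). Hypoxia and glycolysis genes had 17 lower, 1 higher and 2 not called among 20 (median -1.10), and 15 lower and 5 higher with library size alone (median -0.52). Lactate dehydrogenase, Ldh, went from 6283 ± 123 to 101 ± 12.5 CPM (-5.96, SE 0.07), hexokinase Hex-A was at -2.31, the translation inhibitor Thor at -3.61 and triose phosphate isomerase, Tpi, at -1.86. Camera gave adjusted p 4.46e-07 (adjusted p = 0.0600 with an estimated correlation).

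Genes of the Turandot, JAK-STAT and antiviral list had 14 lower, 4 higher and 2 not called among 20 (median -0.88). The numbers were 10 lower and 8 higher with library size alone (median -0.30), so the balance depends on the scaling. Socs36E, a target and inhibitor of JAK-STAT signalling, went from 1522 ± 37.6 to 115 ± 11.1 CPM (-3.73, SE 0.07), with Tep4 at -1.51, vir-1 at -0.86 and Tep2 at -0.78. Camera gave adjusted p 0.00503 (adjusted p = 0.149 with an estimated correlation). The JNK and AP-1 list had 10 lower, 2 higher and 1 not called among 13 (median -0.73), with Gadd45 at -2.95, Ets21C at -1.92 and the JNK phosphatase puc at -1.63, and wgn, a TNF receptor, higher at 1.37. This list had 6 lower and 4 higher with library size alone (median -0.15). Its camera result was adjusted p 0.00503 (adjusted p = 0.345 with an estimated correlation).

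The endoplasmic reticulum stress list was not called by camera (adjusted p 0.217; adjusted p = 0.345 with an estimated correlation). It had 12 lower, 7 higher and 7 not called among 26, and its median moved from -0.14 to 0.01 with upper-quartile factors and 0.44 with library size alone. Its lowest member was Thor, shared with the hypoxia list, at -3.61 on the log2 scale. PPP1R15, which restarts translation after stress, was at -1.50, the stress sensor Ire1 at -1.47 and BI-1 at -1.18. The DNA damage and apoptosis list was not called either (adjusted p 0.577; adjusted p = 0.790 with an estimated correlation). It had 8 lower, 6 higher and 7 not called among 21, with the cell death gene rpr at -4.16, Xrp1 at -1.60, Irbp at -1.20 and the DNA repair gene Fancd2 at 2.26. Its median of -0.15 became 0.42 with library size alone.

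Genes for making ribosomes and those coding for the ribosome's own proteins moved in opposite directions. Of 88 measured cytosolic ribosomal protein genes, 83 fell, 2 rose and 3 were not called (median -0.93; camera adjusted p 2.04e-16; adjusted p = 0.345 with an estimated correlation). RpL3 went from 5631 ± 506 to 2008 ± 427 CPM (-1.51, SE 0.07), RpL22 was at -1.30 and sta at -1.16. Of the ribosomal protein genes 75 were lower and 3 higher with library size alone (median -0.35). RpLP0-like, a member by its prefix only that relates to a ribosome assembly factor, rose (1.37, SE 0.06). Of 55 ribosome biogenesis genes, 47 rose, 5 fell and 3 were not called (median 0.77; camera adjusted p 1.46e-10; adjusted p = 0.0897 with an estimated correlation). CG13185 was at 1.99, the RNA polymerase I subunit RpI135 at 1.77 and l(1)G0020 at 1.43, whereas Nop17l fell (-1.37, SE 0.06).

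Cell cycle and DNA replication genes rose, with 26 of 29 higher, 1 lower and 2 not called (median 1.50; camera adjusted p 9.54e-11; adjusted p = 0.0600 with an estimated correlation). Beside stg, the replicative helicase subunit Mcm6 went from 32.0 ± 1.23 to 155 ± 8.40 CPM (2.28, SE 0.06), the mitotic kinase polo was at 1.50 and cyclin B, CycB, at 1.44. Among 30 chromatin remodelling genes, 23 were higher, 5 lower and 2 not called (median 0.28; camera adjusted p 5.03e-04; adjusted p = 0.0977 with an estimated correlation). Acf was at 1.91, Chd3 at 1.47, dom at 1.09 and Ssrp at 0.74.

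Proteasome genes had 29 lower, 4 higher and 3 not called among 36 (median -0.33; camera adjusted p 1.92e-04; adjusted p = 0.345 with an estimated correlation), with Rpn13 at -0.96, Rpn6 at -0.76, Rpn2 at -0.70 and Prosbeta2 at -0.60. With library size alone the proteasome direction turned, to 22 higher and 3 lower with a median of 0.26, and Prosbeta2 was no longer called. Mitochondrially encoded genes had 14 higher, 2 lower and 2 not called among 18 (median 1.10; camera adjusted p 0.0102; adjusted p = 0.526 with an estimated correlation). mt:ND1 was at 1.51, mt:ND5 at 1.07 and mt:ND3 at 2.34, while the ribosomal RNA mt:lrRNA was at -1.15. Camera did not call this list with library size alone (adjusted p 0.159).

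Plasmatocyte markers, genes of the phagocytic blood cell that S2 cells resemble, had 9 higher, 3 lower and 3 not called among 15 (median 0.53; camera adjusted p 0.0287; adjusted p = 0.182 with an estimated correlation). The extracellular matrix gene Ppn went from 73.5 ± 0.39 to 327 ± 22.5 CPM (2.15, SE 0.04), with Glt at 1.98, Nplp2 at 1.97 and the phagocytic receptor eater at 0.86. The plasmatocyte call ended with library size alone (adjusted p 0.0963), without the filter (0.0516), and without control replicate 1 (0.0546), dsRNA 2 replicate 1 (0.0884) or 2 (0.0828), or dsRNA 3 replicate 2 (0.0814). Lamellocyte markers, genes of the encapsulating blood cell, had 7 lower and 1 higher among 8 (median -1.33; camera adjusted p 0.00512; adjusted p = 0.152 with an estimated correlation). ItgaPS5 was at -2.65, PPO3 at -2.17, Itgbn at -1.42 and cher at -1.24. With library size alone this list had 5 lower and 2 higher (median -0.75).

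The remaining 6 lists were not called by camera with either correlation. Among 27 DEAD-box helicases 15 were higher, 7 lower and 5 not called (adjusted p 0.165; adjusted p = 0.495 with an estimated correlation), and apart from Hlc they included CG7878 at 0.96 and eIF4A at -1.01. Of 40 RNA polymerase II and general transcription factor genes, 13 were higher, 16 lower and 11 not called (adjusted p 0.927; adjusted p = 0.923 with an estimated correlation), with Cdk9 at -1.55, Taf6 at -1.39, CycH at -0.85 and TfIIEalpha at -0.64. The median of that list was 0.01 and its mean -0.03, and its balance turned to 20 higher and 12 lower with upper-quartile factors and 29 higher and 3 lower with library size alone, where TfIIEalpha was not called (adjusted p 0.265). Of 17 starvation and FOXO response genes, 8 were higher, 6 lower and 3 not called (camera adjusted p 0.795, and adjusted p = 0.830 with an estimated correlation). In that list the lipases bmm and Lip4 were at 1.47 and -1.78, Atg8a at -0.94 and Thor, the lowest member, at -3.61. Of 17 ecdysone response genes, 7 were higher, 5 lower and 5 not called (adjusted p 0.769; adjusted p = 0.830 with an estimated correlation), with ImpL2 at -2.40, Sox14 at -2.07, usp at -0.74 and Eip74EF at 1.18. ImpL2 shares 61.9% of its exonic bases with another gene. Markers of ovarian somatic and neuronal cells had 4 higher, 2 lower and 5 not called among 11 (adjusted p 0.510; adjusted p = 0.564 with an estimated correlation), with Fas3 at -6.05, bab2 at -3.33, piwi at 2.24 and fs(1)Yb at 1.07. The 1 crystal cell marker tested, lz, was not called, with 50 counts over the controls and 26 over the Hlc libraries (list adjusted p 0.577; adjusted p = 0.666 with an estimated correlation). lz was called lower without dsRNA 3 replicate 1 (adjusted p 0.0407) and by limma-voom (0.0248).

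Camera called 15 of the 23 lists, 10 lower and 5 higher, and 0 of them with an estimated correlation, where the smallest adjusted p was 0.0600. The estimated correlation was 0.633 for cytosolic ribosomal proteins. It was below the preset 0.01 for other lists that lost their call, at -0.02 for cell cycle, -0.001 for hypoxia and 0.001 for chromatin remodelling genes. For cell cycle genes the unadjusted camera p still went from 1.66e-11 to 0.0047. Correlated members alone therefore do not account for the loss of every call. The correlation was estimated on 3 residual degrees of freedom. A missing call with an estimated correlation therefore does not show that a list was unmoved. The median of each of the 23 lists was higher with library size alone than with TMM. fry, which asks whether members move one way without comparing them with other genes, called 21. In every list the members called when adjusted over the list alone were as many in each direction as those called over all features.

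**Figure D2:**
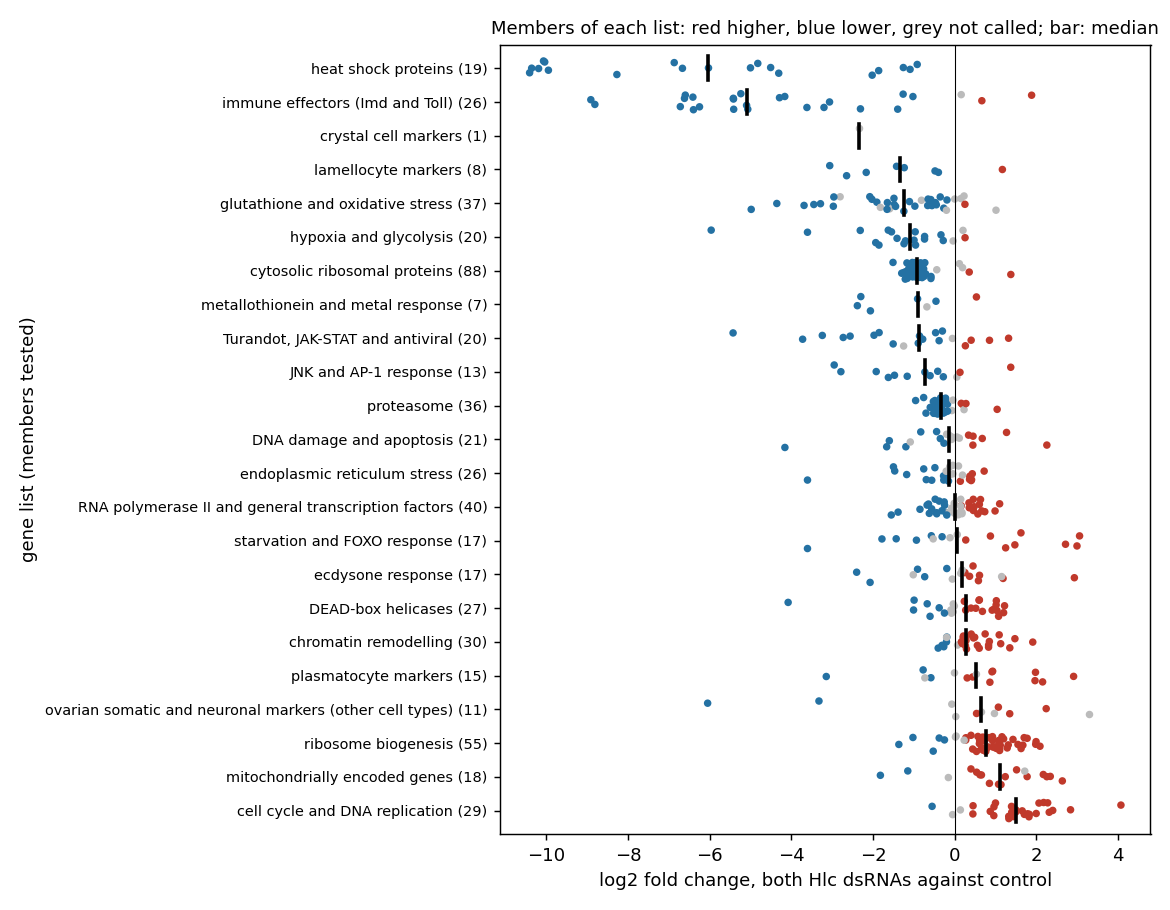
Log2 fold change of each measured member of the 23 gene lists, both Hlc dsRNAs against control, with called rises in red, called falls in blue, members not called in grey and a bar at the median. Heat shock proteins (median -6.03) and immune effectors (-5.08) lie farthest to the left, and cell cycle genes (1.50) farthest to the right.

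Each dsRNA was also compared with control alone, to see whether separate reagents moved the same genes. With dsRNA 2, 6852 features were called (3431 higher, 3421 lower) and with dsRNA 3, 6954 (3380 higher, 3574 lower). The 5 largest falls were the same 5 Hsp70 copies with each reagent, Hsp70Ba at -10.36 and -10.37 and Hsp70Bc at -10.33 and -10.49. Tsp5D (log2 fold change 6.18 with dsRNA 3), GABA-B-R2 (5.37 and 4.88) and pre-mod(mdg4)-H (4.37 and 5.24) were among the 5 largest rises with each. Without control replicate 2, Tsp5D stood at 4.89 with dsRNA 2 and 5.07 with dsRNA 3 and GABA-B-R2 at 4.28 and 3.79. Without control replicate 1 the control of both genes was at 0 counts and the fitted values are no measure. pre-mod(mdg4)-H shares 100% of its exonic bases with another gene and had 4 counts over the controls against 363, so its value is uncertain. With dsRNA 2 its log2 fold change was 0.72 without dsRNA 2 replicate 1, 5.29 without dsRNA 2 replicate 2 and 3.27 without control replicate 2, and with dsRNA 3 it was 4.14 without control replicate 2. Without control replicate 1 its control too was at 0 counts. Its call with dsRNA 2 ended with DESeq2 (adjusted p 0.0609), limma-voom (0.217) and the length trend removed (0.0532), and its call with dsRNA 3 with limma-voom (0.0700). The dsRNA 2 call also ended without control replicate 1 (adjusted p 0.0831) or 2 (0.204), dsRNA 2 replicate 1 (0.686) and dsRNA 3 replicate 1 (0.0789) or 2 (0.0761). With dsRNA 3 it ended without control replicate 1 (0.0544) or 2 (0.120) and dsRNA 3 replicate 1 (0.0697) or 2 (0.0502). TM4SF (3.72 without control replicate 1, and a control at 0 counts without control replicate 2) and btn completed the list for dsRNA 2, and Syn1 and stg that for dsRNA 3. As with both together, upper-quartile factors and library size alone moved the split, to 4068 against 2899 and 6038 against 1619 for dsRNA 2, and to 3968 against 2944 and 6080 against 1710 for dsRNA 3.

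The 2 reagents called 6156 features in the same direction, 2995 higher and 3161 lower, which is 89.8% of the calls with dsRNA 2 and 88.5% of those with dsRNA 3. Independent lists of these lengths would share 1027 higher and 1083 lower. Unchanged groups simulated against the same controls gave on average only 1.35 calls with dsRNA 2 and 1.1 with dsRNA 3. They shared 0.25 features higher and 0.05 lower. With so few calls, the simulation cannot show how much overlap shared controls add to lists of the observed length. Across features, which are not independent replicates, fold changes correlated at Pearson 0.917 and Spearman 0.931, against 0.523 and 0.456 simulated with no effect, and their covariance was 2.60 against 0.11 simulated. The 2 controls could not be split with 2 libraries on each side, so part of the excess may come from sharing them. With a different single control for each reagent, chosen after seeing the data, 5335 and 5109 features changed the same way, where independent lists would share 816 higher and 822 lower, and 803 and 836. Pearson correlations were then 0.631 and 0.632, against 0.894 and 0.906 with the same single control for both. Spearman correlations with the different controls fell less, to 0.791 and 0.774, against 0.931 in the main fit. Pearson also depended on low counts, at 0.738 with no filter and 0.975 with the 1 CPM filter when both controls were used. Features at 0 counts in a lone control have fitted values that are no measure. The drop in Pearson therefore does not show how much sharing the controls adds. NP15.6 (0.18 with dsRNA 2 and -0.19 with dsRNA 3) and CG14695 (0.43 and -0.34) were the 2 features called in opposite directions, named after their values were seen. A test of their difference between the reagents gave adjusted p 0.0739 and 0.0586. Their opposite signs are those of the TMM scale, and falls this small depend on the scaling. With library size alone the median of all features with dsRNA 3 was 0.625, against 0.036 with TMM.

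**Figure D3:**
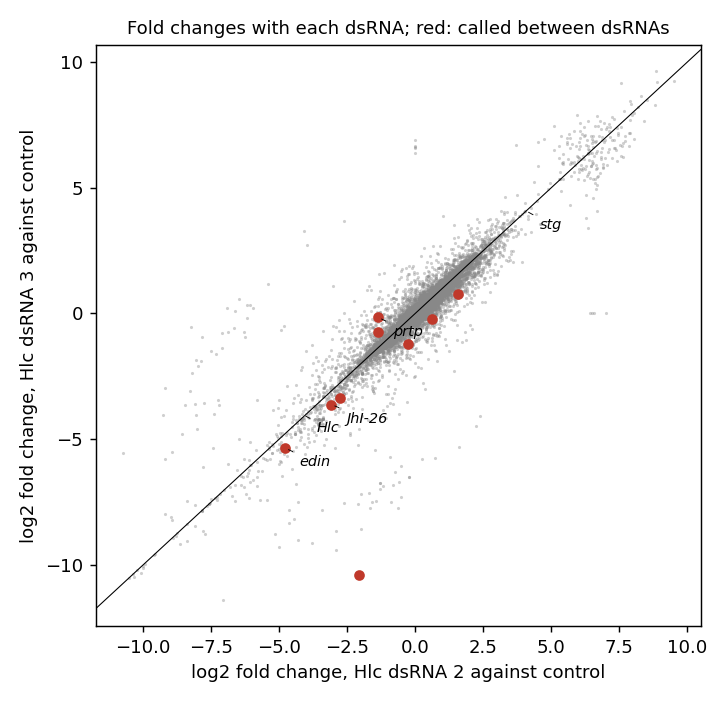
Log2 fold change against control with dsRNA 2 (horizontal) and dsRNA 3 (vertical), 1 point per feature, with the line of equal values and the 9 features called between the dsRNAs in red. The red point for prtp lies above the line, at -1.36 and -0.16.

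Comparing dsRNA 3 with dsRNA 2 directly, prtp differed most firmly. prtp, an endoplasmic reticulum protein that acts as a ligand of the engulfment receptor Draper in the clearance of dying cells, stood at 82.8 ± 2.86 CPM with dsRNA 2 and 190 ± 0.44 CPM with dsRNA 3 (SD, n = 2 each), against 212 ± 12.2 CPM in the controls. Its log2 difference was 1.20 (SE 0.06, adjusted p 0.00180). The immune peptide edin was lower with dsRNA 3 (121 ± 3.43 against 181 ± 5.37 CPM; log2 difference -0.58, SE 0.06, adjusted p 0.0406), as was JhI-26, a gene induced by juvenile hormone (-0.55, SE 0.05, adjusted p 0.0398). The calls of edin (highest adjusted p 0.213) and JhI-26 (0.164) ended without either control, either dsRNA 2 library or dsRNA 3 replicate 2, and among other settings with library size alone, while that of prtp held. JhI-26 shares 70.5% of its exonic bases with another gene.

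In all 9 features were called between the dsRNAs, 2 higher and 7 lower with dsRNA 3, while 2298 had an unadjusted p under 0.05 where 565 would by chance. The count depended strongly on the method, with 1221 by DESeq2, 327 by limma-voom, 172 with the 1 CPM filter, 34 with no filter and 1 with library size alone, with the replicate number as a block or with only the 4 libraries compared, and 88 with element copies summed. It was 1 without control replicate 1, control replicate 2 or dsRNA 3 replicate 2, and 148 without dsRNA 3 replicate 1. A small count in the edgeR fit therefore does not show that the reagents acted alike.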

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

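The test of gene length and both tests of transposable elements were set before their results were seen; the tests of scaling, culture differences, near-identical copies and induced controls were chosen after. The 9 features below are those whose response differed between the 2 Hlc dsRNAs by a test of the difference itself. Log2 differences, dsRNA 3 minus dsRNA 2, were 1.20 for prtp, 0.62 for CG18135, -0.55 for JhI-26, -0.58 for edin, -0.60 for CG15784, -0.80 for the element copy RR48361, -0.82 for CG32625 and -0.97 for CG3168. CG10814 had 0 counts with dsRNA 3 against 84 with dsRNA 2 and 268 in the controls. When bounded by 3 counts over the group it was 31.5-fold lower than with dsRNA 2 (a log2 bound of -4.98). prtp was called in 17 of 17 alternatives (adjusted p 3.94e-61 to 0.0403). Each of the others was called in 7 to 9 of its 15 to 17 alternatives, and 5 of the losses of each came with a library left out. The log2 differences moved little, -0.55 to -0.53 for JhI-26, -0.83 to -0.80 for CG32625, 0.59 to 0.64 for CG18135, -0.65 to -0.55 for CG15784, -0.61 to -0.54 for edin, -0.84 to -0.75 for RR48361 and -1.06 to -0.87 for CG3168.

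The first pattern weighed is that 7321 features differed between control and Hlc dsRNA libraries. A gene length trend as the whole cause is argued against, since 94.2% of called features kept their call and direction after the trend was removed. Under all 4 scalings tried 73.9% of calls held, namely 99.0% of rises (3598 of 3634) and 49.2% of falls (1815 of 3687, 95% interval 47.6% to 50.9%). With library size alone set aside, 85.5% of falls held. The shares by direction are no test of scaling, since no alternative moved fold changes far down. The median of all features was 0.043 with TMM, 0.036 with DESeq2 size factors, 0.188 with upper-quartile factors and 0.623 with library size alone. Rises could therefore hardly be lost, while falls could. Scaling cannot be told apart from a change in level for the rises as a set or for the 1872 falls not held. No value here decides between the scalings. A culture or batch difference cannot be told apart from Hlc loss, since the labels name no batch and replicate deviations did not correlate between groups (highest 0.003), and loss of Hlc, which the design names, stays open beside it.

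The second pattern is that heat shock, immune and other inducible genes were lower in the Hlc libraries. Reads shared between near-identical copies are argued against as the whole cause, because the heat shock and immune lists without those copies had a median log2 fold change of -4.51 over 33 members (quartiles -6.03 and -1.86). Control cultures in an induced state for a reason other than Hlc cannot be told apart from a lower basal level with Hlc dsRNA. Of the 8 lists of metal, heat shock, immune, JAK-STAT, glutathione, endoplasmic reticulum, hypoxia and JNK genes, 7 were lower by camera with the preset correlation, which either explanation would give, but 0 were called with an estimated correlation (lowest adjusted p 0.0600). The DNA damage (adjusted p 0.577) and starvation (0.795) lists, not counted among the 8, were not called by camera, and no untreated cells were analysed here.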

How the results depend on the processing

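The fit without the length trend, the fit with element copies summed and the split of the controls were chosen after seeing the data. The counts against control and the count changed the same way stayed within 1.5 times under every alternative run (both dsRNAs 6488 to 8146). Hlc stayed called, at -3.50 to -4.15. The count between dsRNA 3 and dsRNA 2, 9 features, became 1 with library size alone, 34 with no filter, 172 with the 1 CPM filter, 1221 with DESeq2, 327 with limma-voom, 1 with only the groups compared and 88 with element copies summed, and ran from 1 to 148 with libraries left out; the cause was not tested. The correlation of the dsRNAs' fold changes was 0.738 with no filter and 0.975 with the 1 CPM filter, 0.631 and 0.632 with a different single control for each dsRNA, and 0.789 to 0.906 with libraries left out, against an SD of 0.0492 over those left-out values, a measure of spread chosen after seeing the data. List calls went from 15 to 0 with an estimated correlation, and fry called 21 and its mixed version 22. A lone library left in a group was assumed to vary like the other groups.

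Replicate numbers did not pair the libraries (correlations of deviations -0.045, 0.003 and -0.032). With the replicate number as a block, 7099 features were called with both dsRNAs and 1 between dsRNAs. ZnT86D turned to 0.12 and the proteasome median to 0.26 with library size alone. fry gave the opposite direction to camera for the starvation (median 0.0614), ecdysone (0.18) and ovarian and neuronal (0.65) lists (adjusted p 0.0297, 0.0174 and 0.0246). Named genes against control lost a call in 22 cases (ZnT86D among them, with its sign turned), gained one in 2 and kept direction and side of the threshold in 2039. Genes called between dsRNAs lost the call in 66 cases and kept it in 84, and DESeq2 gave CG10814 no adjusted p. Depth limits genes with few counts in the lower group, such as Tsp5D with 5, whose ratio has a counting interval of 31.0 to 224.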

Other observations

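The 20 families here were picked by symbol, and their tests chosen, after seeing the data; both tests of element copies were set before their results were seen. Of 18 aminoacyl-tRNA synthetase genes, 17 fell and 1 was not called (median log2 fold change -1.23; camera adjusted p 1.62e-07 over 20 families; adjusted p = 0.437 with an estimated correlation). Of 36 translation initiation factor genes, 29 fell, 2 rose and 5 were not called (median -0.92; adjusted p 1.76e-07; adjusted p = 0.248 with an estimated correlation). All 8 genes of the chaperonin CCT fell (median -0.61; adjusted p 0.00268; adjusted p = 0.370 with an estimated correlation), as did 21 of 25 Rab GTPases, with 4 higher (median -0.54; adjusted p 9.73e-04; adjusted p = 0.248 with an estimated correlation). With library size alone the synthetases still had 14 lower and 2 higher and the initiation factors 21 lower and 10 higher, but CCT had 3 lower and 2 higher and the Rab genes 6 lower and 6 higher, so the last 2 directions depend on the scaling. Of the 20 families tried, camera called 9, and 0 with an estimated correlation (lowest adjusted p 0.248).

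Of 12 DNA polymerase subunits, 9 rose and 3 fell (median 1.70; adjusted p 0.0204; adjusted p = 0.297 with an estimated correlation), and of 24 nucleoporins, 17 rose, 5 fell and 2 were not called (median 0.44; adjusted p 0.00497; adjusted p = 0.297 with an estimated correlation). Small nucleolar RNAs, which guide ribosomal RNA modification, had 37 higher, 2 lower and 51 not called of 90, while small nuclear RNAs had 9 lower and 2 not called of 11. Library size alone kept these directions, with 59 higher and 1 lower and with 8 lower and 0 higher. Both classes lack poly(A) tails as mature RNA, so their counts in poly(A) libraries are a small and uncertain sample.

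The third pattern weighed is that more transposable element copies were higher than lower in the Hlc libraries. Of 1376 copies, 593 were higher, 64 lower and 719 not called. Reads of host genes counted at inserted copies are argued against as the whole cause, since 76.9% of 619 copies outside annotated genes had a fold change above 0 (95% interval 73.4% to 80.2%), although copies share reads and are not independent. A rise of only a few families is argued against as well, since after summing copies 76 of 124 named families rose and 8 fell (median 0.79), while of 19 single features without a family name 10 rose and 1 fell. The 1731 family went from 698 ± 91.5 to 3271 ± 223 CPM and 3S18 from 1686 ± 193 to 5991 ± 718 CPM, whereas copia, the most abundant of these, went from 50710 ± 472 to 28880 ± 3772 CPM. Elements together made up 4.97% and 5.32% of control counts and 6.41% to 6.82% of counts in the Hlc libraries. With TMM factors of 0.751 and 0.778 against 1.13 to 1.16, however, their total was lower in the Hlc libraries. The direction of the total thus depends on the scaling. copia weighs most in that total, since the next most abundant family in the controls, blood, stood at 1843 ± 317 CPM and rose. Among single copies, rises outnumbered falls with library size alone as well (827 against 49). A culture difference between control and Hlc cells stays open here too, as does loss of Hlc.

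Fold changes followed abundance among protein-coding genes, with a median of 0.19 in the lowest of 10 equal classes by mean CPM and -0.49 in the highest. With library size alone both classes lay above 0, at 0.76 and 0.09, so the sign in the highest class depends on the scaling. Position was examined in 6622 protein-coding genes kept by a cut on mean CPM, with log2 fold changes capped at both ends. Neighbouring genes on a chromosome arm correlated at 0.11, above the range of 1000 shuffles (-0.02 to 0.03). Genes 2 positions apart correlated at 0.043, also above it (-0.02 to 0.03), and genes 20 positions apart at 0.008, within it (-0.02 to 0.03). Overlapping genes and near-identical copies were kept, so the value for neighbours does not separate position from reads divided between them.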
